A study of Bos taurus with 12 samples.

How the data were processed

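RNA sequencing covered 4 groups of 3 libraries each, per the labels: bovine fetal fibroblasts, and pools of 8 embryos at the 8-cell stage from IVF, SCNT and SCNT with KDM5B overexpression. Groups were taken from the sample titles, since the sample group label of the fibroblasts names SCNT embryos. Embryos were lysed directly and their cDNA was amplified before library construction, per the labels' protocols. The series' design text puts fibroblasts on a BGISEQ instrument and embryos on a HiSeq, while the protocol text of the labels names a HiSeq for all samples. No library batches or dates are given in the labels.

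The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library), deposited by the authors in 1 table with 1 column per group. That the columns are means of 3 libraries is read from the values: 100% of fibroblast values and 99.9955% of values in each embryo column are whole multiples of 0.01 divided by 3, with a tolerance of 0.001 on the value times 300. The submitters' processing notes name bcl2fastq 2.16, HISAT 0.1.6, StringTie 1.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the genome build UMD3.1, without saying which step each was used for. Filters and the annotation are not given in the sources used here. Means keep no read totals, so depth and the precision it gives are unknown, and a gene listed at 0 is reported as such, without a fold. Amplification of cDNA from few cells and normalization to each library's total can shift low genes and the scale of a whole column, which is why centred splits are given beside those of the deposited values.

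Before the data were examined, limma tests on log2(FPKM + 1) across libraries, with an adjusted p threshold of 0.05, were planned, together with tests of fixed gene lists and markers. None could be fitted, because each group has 1 value, and no p-value is given. Their place was taken by differences of log2(FPKM + 1) between group means, with genes counted at 2-fold (donor classes at 4-fold). That size rule was set after the form of the table was seen. Fold limits on this scale understate differences of low genes. Genes were kept with FPKM of at least 1 in any embryo group (14836) or, for fibroblasts against IVF, in either group (15634), in place of the planned limit of 1 in 3 libraries.

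The IDs (17643 Ensembl and 4802 of the authors' own) could not be matched to names: the gene table used, of assembly ARS-UCD2.0 with 37063 entries, has 0 entries in its Ensembl column. Gene names, fixed lists and the KDM5B transcript were therefore not analysed here. Instead of the planned rule for named genes, which needs symbols and replicates, the 2 Ensembl IDs with the largest difference each way in a comparison were named, among those with at least 5 FPKM in the higher group.

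Donor classes were genes at least 4-fold apart between fibroblasts and IVF, or genes at 10 FPKM or more and under 1 in fibroblasts. List medians were set against 10000 random lists of the same size, matched in 20 bins of mean embryo expression. Comparisons that share a column were set beside 100 simulations of unchanged groups. Where IVF was shared, noise was as large as the SCNT to IVF spread in each expression bin, split equally between the columns or, as a limit, all placed in IVF with the SCNT values and the median difference kept. Where SCNT was shared, noise was as large as the spread between the clone groups, split equally or all placed in SCNT. The code that counts genes was checked for SCNT against IVF on the 12582 genes at 1 FPKM or more in IVF, with all columns set to the IVF values and 200 genes set at 4-fold. It returned those 200 and 0 others, which, without noise, tests the code and says nothing of errors of the 2-fold rule on real means.

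Alternatives were pseudocounts of 0.1 and 5, no filter, mean FPKM of at least 5, rescaling to a sum of 1000000 (TPM), quantile normalization, columns centred on the median log2 value relative to the gene means, and other donor classes. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.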

Results

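Gene expression was measured by RNA sequencing in Holstein cattle, in fetal fibroblasts and in pools of 8 embryos at the 8-cell stage. Embryos were made by in vitro fertilisation (IVF) or by somatic cell nuclear transfer (SCNT), in which the nucleus of a body cell is placed in an egg without its own nucleus. A further group of cloned embryos overexpressed KDM5B, an enzyme that removes methyl groups from lysine 4 of histone H3, a mark found at active genes. The labels listed 3 libraries in each of the 4 groups, 12 in all. The deposited table held 1 value per group and gene, the authors' mean in FPKM, so no replicate values, SD or test could be given, and every difference reported is a difference between group means with no replicate check. The series title gives as its subject genes of somatic memory in nuclear reprogramming.

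The table listed 22445 loci, of which 17643 carried Ensembl gene IDs and 4802 carried the authors' own locus IDs. The IDs were not paired with gene names, and the gene table used here has no entries in its Ensembl column, so they could not be matched to names. KDM5B itself, the fixed gene lists and markers of other cell types were therefore not analysed here, and single genes are given by ID. Library depth is unknown, since FPKM means keep no read totals. FPKM of at least 1 was reached by 11616 loci in fibroblasts, 12582 in IVF embryos, 11262 in SCNT embryos and 12121 in SCNT embryos with KDM5B.

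The groups of cloned embryos resembled each other more than either resembled IVF embryos. Across 14836 genes with FPKM of at least 1 in an embryo group, Pearson's r of log2(FPKM + 1) was 0.97 between SCNT with and without KDM5B, 0.72 between IVF and SCNT, and 0.74 between IVF and SCNT with KDM5B. Spearman's rho was 0.95, 0.65 and 0.67 for the same pairs. Fibroblasts were farther from all embryos, with r of 0.40 to IVF, 0.49 to SCNT and 0.50 to SCNT with KDM5B, and rho of 0.39, 0.48 and 0.49. These 6 correlations are across genes, which are not independent replicates.

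The first comparison asked what cloned embryos express differently from fertilised embryos of the same stage. SCNT and IVF means lay at least 2-fold apart on the log2(FPKM + 1) scale for 8897 of the 14836 genes, 3454 higher and 5443 lower in SCNT. The count was 10675 at a pseudocount of 0.1 and 4833 at 5, and 5012 of the 7547 genes at a mean FPKM of at least 5. ENSBTAG00000038783.2 was listed at 0 in IVF, at 648 FPKM in SCNT and at 509 in fibroblasts. ENSBTAG00000039456.2 stood at 0.807 FPKM in IVF, 323 in SCNT and 335 in fibroblasts, a ratio of 401 between SCNT and IVF. In the other direction, ENSBTAG00000037881.1 stood at 562 FPKM in IVF and 15.9 in SCNT, a ratio of 35.3, and ENSBTAG00000001812.5 at 676 and 21.0, a ratio of 32.3. Both were listed at 0 in fibroblasts and at the same 73.9433 FPKM in SCNT with KDM5B, so they may not be independent examples. The median log2 difference over all genes was -0.45, so the split depended on scaling. With each column centred on its median log2 value relative to the gene means, 4690 genes were higher and 3574 lower. The share of higher genes then went from 38.8% to 56.8%. With values rescaled to TPM it was 34.5%, and after quantile normalization 47.0%.

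Genes of IVF embryos that both clone groups barely expressed were a small class. FPKM was at least 5 in IVF and under 1 in both clone groups for 158 genes, of which 119 (75.3%) were also under 1 in fibroblasts. The opposite class, at least 5 in both clone groups and under 1 in IVF, held 349 genes, of which 112 (32.1%) reached 5 in fibroblasts and 200 (57.3%) were under 1 there. All 3 embryo groups reached 5 for 5080 genes, 73.3% of which also reached 5 in fibroblasts. The authors' own loci made up 70 of the 158, 135 of the 349 and 296 of the 5080 genes. In fibroblasts 16.0% of all such loci reached 1 FPKM, against 61.5% of Ensembl IDs. The fibroblast shares of these classes may therefore partly reflect their mix of locus types.

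**Figure D1:**
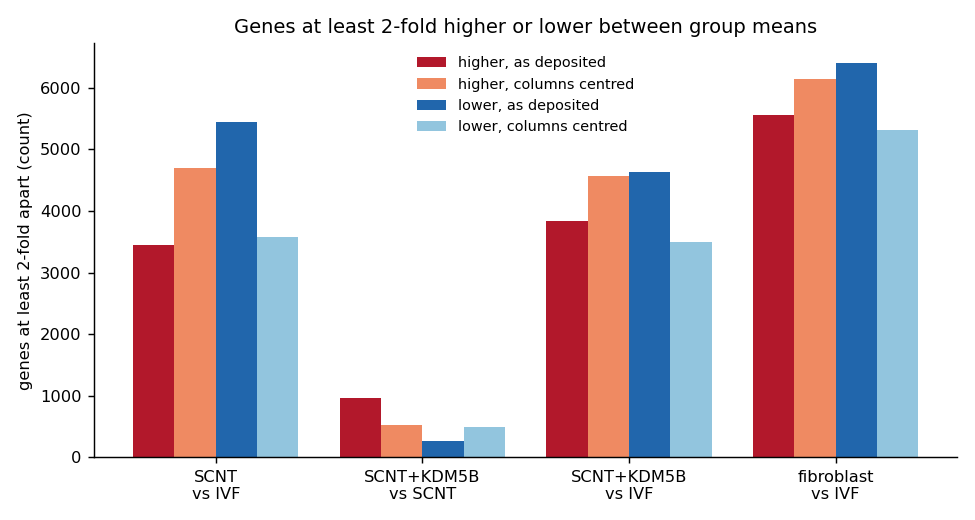
Number of genes whose group means lay at least 2-fold apart on the log2(FPKM + 1) scale, by comparison. Bars give genes higher and lower in the group named first, as deposited and with columns centred on their median log2 value relative to the gene means. SCNT with and without KDM5B differed for 1227 genes as deposited, and SCNT and IVF for 8897; centring turned the SCNT and IVF split from 3454 higher and 5443 lower to 4690 and 3574.

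The fibroblast and IVF means defined genes high or low in the donor cell type. Over 15634 genes with FPKM of at least 1 in either group, 5559 were at least 2-fold higher and 6401 at least 2-fold lower in fibroblasts (6144 and 5319 with columns centred), and 3682 and 3548 were apart by at least 4-fold. ENSBTAG00000017312.3 was listed at 7070 FPKM in fibroblasts and 0 in IVF, and ENSBTAG00000021466.5 at 4287 and 0.0867. In SCNT embryos the same IDs stood at 0.19 and 0.813 FPKM. ENSBTAG00000034346.2 was listed at 0 in fibroblasts and 24421 in IVF, and ENSBTAG00000027348.3 at 0 and 11949; SCNT embryos held 5808 and 2414 FPKM of them. Of the authors' own loci, 285 were higher and 1808 lower in fibroblasts. The series' design text puts fibroblasts on a BGISEQ and embryos on a HiSeq instrument, while the protocol text names a HiSeq for all. If the design text is right, instrument and cell type cannot be told apart in this comparison.

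Somatic memory was examined first by classes that combine both comparisons. Of 2146 genes at least 4-fold higher in fibroblasts than in IVF, 800 (37.3%) were at least 2-fold higher in SCNT than in IVF and 380 were at least 2-fold lower. Of 3548 genes at least 4-fold lower in fibroblasts, 2403 (67.7%) were at least 2-fold lower in SCNT and 289 were higher. Both comparisons share the IVF column. Unchanged SCNT and IVF groups simulated with noise as large as their whole spread, split equally, gave 913 genes in the first class (at most 993 in 100 draws) and 1535 in the second (at most 1621), and independent lists would give 428 and 1442 over the 13389 genes measured in both. With columns centred the first count was 1176 of 2526 genes, against 952 simulated (at most 1009) and 676 for independent lists. The second was then 1768 of 2988, against 1474 (at most 1566) and 798. The equal-noise draws carried no shift between the columns, while the deposited SCNT and IVF columns differed by a median of -0.45. Their numbers are therefore not like for like with the counts as deposited. With columns centred, both classes lay above the highest draw. With all noise placed in IVF the simulation gave 947 and 2725 genes as deposited and 1368 and 2072 centred, all above the observed numbers. The covariance of the comparisons was 1.85, against 1.44 with noise split equally, a difference of 0.41, and 2.87 with all noise in IVF, and part of the excess over independent lists may come from the shared IVF libraries, which the single column does not allow to be split. With donor classes taken instead from fibroblasts against SCNT with KDM5B, an alternative chosen after seeing the data, the directions turned: 192 of 1895 donor-high genes were higher and 805 lower in SCNT, and 894 of 3262 donor-low genes were lower and 1424 higher. That class leans the other way by construction, as the KDM5B column follows the SCNT column (r of 0.97).

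Classes taken from the fibroblast column alone share no embryo column. Genes at 10 FPKM or more in fibroblasts had a median SCNT minus IVF log2 difference of -0.11, with 1446 of 5085 higher and 1495 lower. Genes under 1 FPKM in fibroblasts had a median of -0.86, with 1098 of 5465 higher and 2487 lower. Among 10000 random lists of the same size matched on embryo expression, the first median stood at percentile 99.78 (random median -0.18, range -0.29 to -0.09) and the second at percentile 0 (-0.67, -0.74 to -0.60). The class medians differed by 0.75, and those of lists matched on mean embryo expression by 0.49. That mean includes both clone columns as well as IVF, so the matching partly depends on the SCNT to IVF difference itself. The 0.49 and the percentiles therefore do not separate expression level from that difference. At pseudocounts of 0.1 and 5 the class medians differed by 1.30 and 0.21. With columns centred, 1877 genes were higher and 974 lower in the first class, and 1526 and 1607 in the second. In the 655 genes at 100 FPKM or more in fibroblasts the median was 0.56, and in the 3487 genes under 0.1 it was -1.02.

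**Figure D2:**
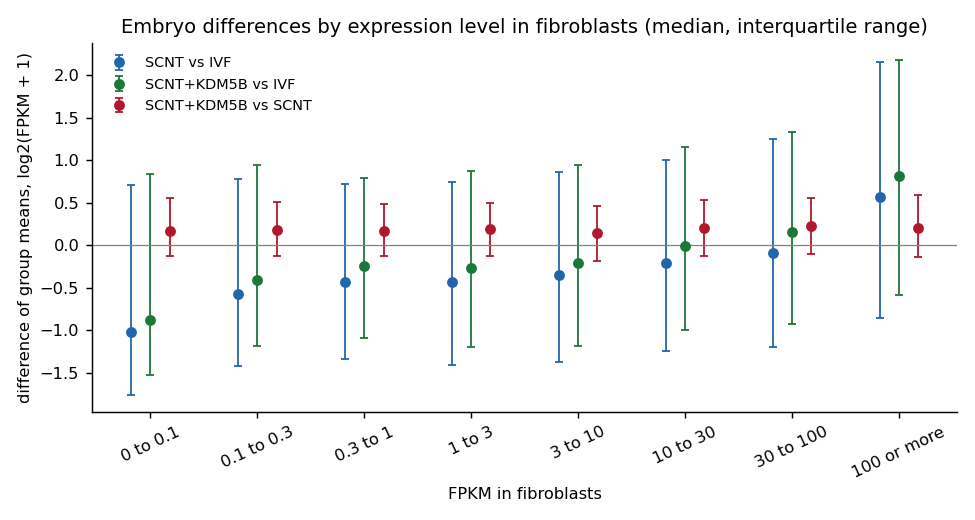
Median difference of group means on the log2(FPKM + 1) scale (points) and interquartile range over genes (lines), by FPKM in fibroblasts, for SCNT against IVF, SCNT with KDM5B against IVF, and SCNT with KDM5B against SCNT. Medians against IVF went from -1.02 to 0.56 for SCNT between the lowest and the highest fibroblast class, and those between the clone groups stayed between 0.14 and 0.22.

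The next comparison asked what KDM5B overexpression did in cloned embryos. The means of SCNT with KDM5B and SCNT were at least 2-fold apart for 1227 genes (8.27%), 959 higher and 268 lower with KDM5B. ENSBTAG00000023823.1 stood at 301 FPKM with KDM5B and 1.87 without, a ratio of 161, and was listed at 0 in IVF and 24.2 in fibroblasts. ENSBTAG00000031731.2 stood at 103 and 0.28 FPKM, a ratio of 366, and was listed at 0 in both IVF and fibroblasts. ENSBTAG00000047768.1 was listed at 24.3 FPKM in SCNT and 0 with KDM5B, and ENSBTAG00000001745.3 at 12.1 and 0.98, a ratio of 12.4; fibroblasts held 79.6 and 1987 FPKM of these. The median over all genes was 0.18, and with columns centred 520 genes were higher and 495 lower, which moved the share of higher genes from 78.2% to 51.2%. The pseudocount also set the count, which was 3113 at 0.1 and 341 at 5.

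Genes that differed between SCNT and IVF were then followed into the KDM5B group. Of the 8897 genes, 5959 (67.0%) had a KDM5B mean on the IVF side of the SCNT mean, and 652 (7.33%) did so by at least 2-fold. Of the 3454 genes higher in SCNT the share was 51.8%, and of the 5443 lower in SCNT it was 76.6%. With columns centred, which redraws the classes, the shares were 63.7% of 4690 higher genes and 65.5% of 3574 lower genes. Both comparisons use the SCNT column with opposite sign. Clone groups simulated without an effect gave 58.4% (at most 59.6%) with equal noise in both, and 65.6% with all noise in SCNT, against 67.0% as deposited and 64.4% centred. The simulations carried no shift between the clone columns, so the centred share is the closer comparison. It lay above the highest draw with equal noise and below the 65.6% with all noise in SCNT. The covariance was -0.28, against -0.16 with equal noise, a difference of -0.13, and -0.31 with all noise in SCNT.

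The donor classes were followed in the same way. The median KDM5B minus SCNT difference was 0.26 over the whole class of 2146 donor-high genes (random lists 0.16 to 0.24) and 0.19 over the 3548 donor-low genes (0.13 to 0.20), against 0.18 over all genes. It was 0.21 for genes at 10 FPKM or more in fibroblasts and 0.17 for genes under 1, an order that turned at a pseudocount of 0.1. The 800 donor-high genes that were higher in SCNT had a median SCNT minus IVF difference of 2.09 and a median KDM5B minus SCNT difference of 0.12, and 47 came within 2-fold of IVF. Their choice by a high SCNT value pulls the second median down. The share of them on the IVF side of the SCNT mean with KDM5B turned with the scaling, from 40.5% as deposited to 57.5% with columns centred; clone groups without an effect gave 56.1% (at most 60.5%) with equal noise and 61.9% with all noise in SCNT. The 2403 donor-low genes that were lower in SCNT had medians of -2.11 and 0.31, and 252 came within 2-fold of IVF. Their share was 73.4% as deposited and 59.5% with columns centred. Clone groups without an effect gave 53.9% (at most 56.1%) with equal noise and 57.9% (at most 60.7%) with all noise in SCNT. The centred share lay above the highest draw with equal noise and below the highest with all noise in SCNT.

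Of 473 genes at 5 FPKM or more in IVF and under 1 in SCNT, 315 were at 1 or more with KDM5B and 3 reached 5. In reverse, 198 genes at 5 or more in IVF were under 1 with KDM5B, of which 40 were at 1 or more in SCNT and 0 reached 5. Of 419 genes at 5 or more in SCNT and under 1 in IVF, 70 were under 5 with KDM5B and 9 were under 1. In reverse, 476 genes at 5 or more with KDM5B were under 1 in IVF, of which 127 were under 5 in SCNT and 9 were under 1. Genes picked by a low or high value in 1 column tend to be less extreme in another, and the whole KDM5B column lay higher by a median of 0.18.

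The last comparison asked how far cloned embryos with KDM5B remained from fertilised embryos. SCNT with KDM5B and IVF means were at least 2-fold apart for 8471 genes (57.1%), 3844 higher and 4627 lower. ENSBTAG00000038783.2 and ENSBTAG00000023823.1 were listed at 0 in IVF and at 727 and 301 FPKM with KDM5B. ENSBTAG00000035012.3 was listed at 29.7 FPKM in IVF and 0 in the other 3 groups, and ENSBTAG00000009472.3 at 41.6 in IVF and 1.49 with KDM5B, a ratio of 28.0. With columns centred, 4569 genes were higher and 3493 lower, and the share of higher genes went from 45.4% to 56.7%. Genes higher than IVF in both clone groups numbered 2992 and genes lower in both 4241. Unchanged groups simulated with equal noise against the shared IVF column gave 1868 (at most 1950) and 1876 (at most 1970), and independent lists 895 and 1698. The clone columns differed by a root mean square log2 difference of only 0.591, so they held less independent noise than the equal split put there. A large overlap follows from that likeness, and neither these draws nor independent lists allow for it. The equal-noise draws were also nearly balanced, while the deposited medians against IVF were -0.45 for SCNT and -0.25 with KDM5B. They are therefore not like for like with the counts as deposited. With all noise in IVF and the median difference kept, the simulation gave 2368 (at most 2507) and 4293 (at most 4404). The 2992 genes exceeded the first limit, and the 4241 genes did not exceed the second. The noise was drawn symmetric, while the SCNT to IVF differences were skewed upward, with quartiles of -1.42 and 0.90 around the median of -0.45. Exceeding the first limit may come from that skew and decides nothing. Part of the excess over independent lists may thus come from the shared IVF libraries. With columns centred these limits were 3287 and 3244, and no observed count is given on that scale.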

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

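Of the values that answer a comparison, 33 under the alternatives stayed within 1.5 times of those reported and 17 moved. Most are counts, which have no sign. Those that stayed include the counts without a filter, which could not change. They also include the shares of genes nearer to IVF with KDM5B, which this rule could label as moved only after a large fall. The balance of higher and lower genes turned with columns centred in each comparison against IVF. It also turned at a mean FPKM of at least 5 for KDM5B and fibroblasts against IVF, and at pseudocount 5 and as TPM for fibroblasts. With a pseudocount of 5, which shrinks differences of low genes, counts of genes 2-fold apart were 4833 for SCNT against IVF, 341 for KDM5B against SCNT, 4611 for KDM5B against IVF and 7799 for fibroblasts against IVF. With genes at a mean FPKM of at least 5, so fewer genes, they were 5012, 719, 4890 and 7410. A pseudocount of 0.1 gave 3113 for KDM5B against SCNT. Genes high in fibroblasts and higher in SCNT numbered 323 at pseudocount 5, 1446 (1495 lower) with the class from fibroblast FPKM alone, and 192 with the class from fibroblasts against SCNT with KDM5B, an alternative chosen after seeing the data, which turned the balance of both donor classes. Genes low in both numbered 3796 at pseudocount 0.1, 1211 at 5, and 894 with that last class. The difference between the medians of the fibroblast classes in SCNT against IVF, 0.75 as reported (0.49 between lists matched on expression), was 1.30 at pseudocount 0.1 and 0.21 at 5. For KDM5B against SCNT it was 0.04 at pseudocount 1 and -0.0927 at pseudocount 0.1; the cause was not tested. Leaving the filter out changed no count, since no gene under 1 FPKM in every group can reach a 2-fold difference at pseudocount 1.

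No paired analysis was possible because the columns are group means and carry no replicate numbers. Leaving out replicates, library weights, variance trends, other sets of samples in the fit, classes without a fold limit and gene list tests were not run for the same reason or for lack of gene names. Depth is unknown and its limits could not be given.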

Other observations

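All tests in this part were chosen after the results were seen.

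Loci under the authors' own IDs reached 1 FPKM more often in embryos than in fibroblasts. FPKM of at least 1 was reached by 16.0% of these 4802 loci in fibroblasts, against 50.2% in IVF, 40.9% in SCNT and 46.5% in SCNT with KDM5B, while for Ensembl IDs the shares were 61.5%, 57.6%, 52.7% and 56.1%. Over the 3524 such loci kept in embryos, the median SCNT minus IVF log2 difference was -0.36, above all 10000 matched random lists (-0.78 to -0.60). The expression used for matching includes both clone columns, so it partly depends on that difference. Their median KDM5B minus SCNT difference, 0.140, was below all 10000 matched lists (0.144 to 0.209). Whether the authors assembled these loci from embryo libraries, fibroblast libraries or both is not given in the sources used here.

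The IVF column was the most concentrated. ENSBTAG00000038488.2, singled out after its values were seen, held 12.2% of all IVF FPKM (94337), against 3.46% in SCNT (30632), 2.45% in SCNT with KDM5B (21778) and 0.477% in fibroblasts (2520). The 10 most abundant loci held 25.2% of IVF FPKM, 17.8% of SCNT, 16.0% of SCNT with KDM5B and 9.02% of fibroblast FPKM. Of 296 genes at 5 FPKM or more in fibroblasts and listed at 0 in IVF, 143 were above 0 in SCNT and 189 with KDM5B, and 29 and 26 reached 1 FPKM. Genes picked at 0 in IVF can only be equal or higher elsewhere. In reverse, 334 genes at 5 FPKM or more in fibroblasts were listed at 0 in SCNT, of which 181 were above 0 in IVF and 5 reached 1 FPKM there. With KDM5B, 206 such genes were listed at 0. Genes at 5 FPKM or more in all 3 embryo groups and listed at 0 in fibroblasts numbered 219.

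The clone columns lay close to each other and far from IVF: the root mean square log2 difference of SCNT and IVF was 2.89 times that between the clone groups, and that of SCNT with KDM5B and IVF 2.74 times. A few abundant genes taking much of the IVF signal would shift all other genes by 1 factor, and centring left the root mean square at 1.71. A separate library batch for IVF stays open, since the labels told 0 batches apart among embryo samples and batch and group cannot be told apart. The way the embryos were made, which the design names, also stays open.

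Genes high in fibroblasts and higher in SCNT than in IVF could reflect fibroblast RNA carried into the embryo at 1 share for all transcripts. The 800 genes would need a share of 36.5%, the median of their SCNT excess over their fibroblast level. Over 22 transcripts at 500 FPKM or more in fibroblasts and under 1 in IVF, the median share was 0.0156% (interquartile range 0.00275% to 0.102%). Of these, 21 of 22 lay below the share needed, which argues against uniform carry-over at that share as the source of the 800 genes. The share needed comes from genes picked for being higher in SCNT than in IVF, which may inflate it. A smaller uniform carry-over was not tested. Noise in the shared IVF column stays open for these genes, since 1 column shows no noise of its own. With columns centred their number was above that simulated with equal noise (1176 against 952) and below that with all noise in IVF (1368). As deposited it was 800, below the 947 with all noise in IVF. The equal-noise number of 913 lacks the column shift and is not like for like. Both simulations took the whole SCNT to IVF spread as noise, so they cannot decide the question. The clone columns differed by a root mean square of only 0.591, so SCNT held less independent noise than the equal split put there. Transcripts that persist to different degrees and transcription from the donor genome also stay open, untested.

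Genes apart between SCNT and IVF lay nearer to IVF with KDM5B, more often where they were lower in SCNT, by 24.9 percentage points as deposited. The 5939 genes under 2-fold apart between SCNT and IVF, outside the pattern, had a median KDM5B minus SCNT difference of 0.17, and taking this off left -3.41 points over the same genes (61.2% of lower and 64.6% of higher genes). A shift of the whole column, technical or not, may thus account for the asymmetry. For the approach to IVF itself, the covariance of -0.283 lay between what equal noise in both clone columns gives (-0.155) and the limit with all noise in SCNT (-0.314). Noise in the shared SCNT libraries and an effect of KDM5B therefore cannot be told apart without values per library.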
